A study of Mus musculus with 2 samples.

How the data were processed

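The samples were 2 single-cell libraries of whole mouse tumors, 1 per genotype, each from pooled tumors of 3 mice, sorted for live cells by DAPI before 10X Genomics capture, per the labels' protocols. Cell Ranger 3.0.0 and Seurat 3.1.4 with mm10/GRCm38 are listed per the submitters' processing notes, with no role or order. The deposited values are a scaled score per gene and cell for 2000 genes in 5196 fl/fl and 4577 cKO cells, and the deposited UMAP coordinates are a second kind of score, with 2 per cell. No filter on cells and no doublet removal is stated in the sources. The values had a maximum of exactly 10 and a minimum of -25.91. In the fl/fl library each gene had a lowest value shared by many cells (a median over genes of 96.0% of cells), which was taken as its zero level. In the cKO library a median of 55.7% of cells had that value and 15.3% lay below it. A correction of the cKO library toward the fl/fl library, as in batch integration, was inferred from these values and from simulated data, and no source states it.

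Cells were assigned to a library by the suffix of their name. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9. Both libraries were clustered together from 30 principal components of the scaled values, 15 neighbours and the Leiden method at resolution 1. Clusters were named from marker lists. A cluster took the class with the highest mean marker difference if this was at least 0.5, the next class was below 0.5 times that value, at least 3 markers were measured, and its 10 leading genes did not hold more markers of another class than of its own. The DC subtypes counted as 1 family. The marker and gene lists, the comparisons and most alternatives were fixed before the data were examined. The naming thresholds, the DC family, the Cr2/Vpreb3 class (Ighm, Cr2, Vpreb3, Iglc1, Iglc2, Iglc3), the NK-like comparison and the comparison of single clusters were chosen after seeing the data. No cluster of the main clustering was named fibroblast, acinar, endothelial or mast cell. No mural or B cell marker was measured. Cells with at least 3 markers at least 1 above the fl/fl zero level from each of 2 families of classes were called possible doublets. The cKO values had been moved, so the 2 counts do not compare doublet rates. They were 99 cells (1.91%) of the fl/fl and 39 cells (0.85%) of the cKO library, and they were kept except in 1 alternative.

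Shares carry exact Clopper-Pearson 95% intervals. For each class with at least 50 cells per library, the difference per gene was the mean cKO value minus the mean fl/fl value. Named genes were, by a fixed rule, Ahr and Lyz2, the 10 highest and 10 lowest differences among genes above zero in at least 5% of fl/fl cells of the class, and up to 4 members of each list with the largest absolute difference, and only Ahr, Lyz2 and list members where a library had under 200 cells of the class. The rule called for 5% in either library, but no zero level was kept in the cKO library. Genes named for clusters 16 and 17 were chosen after their values were seen, from the fixed lists. Members of a list were counted as higher or lower from a difference of 0.1, and a list's median was placed among 10000 random lists matched on decile of the fl/fl mean, as a description of these libraries only. The lists were AHR-induced genes, alternative activation, inflammatory cytokines and mediators, interferon response, MHC class II, lipid-associated macrophage, complement, myeloid chemokines, hypoxia and glycolysis, T cell effector, T cell inhibitory receptors, naive and memory T cell, regulatory T cell, cell cycle, and dissociation and stress. No gene of the MHC class I and mitochondrial lists was measured, so RNA quality could not be judged from them. The fibroblast lists were not used here because no fibroblast class was named in the main clustering.

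The correction was removed from a cKO value by subtracting the 0.3 quantile of the gene over the 30 nearest cKO cells, per cluster, with clusters pooled by their cKO cells, for genes above zero in under 40% of fl/fl cells of every cluster of the class. This estimate was developed after seeing the data. Values of the study under 2 forms of it had been looked at before 3 forms were compared on simulated data, by a rule set before that comparison, and the form with the lowest error for genes above zero in 5% to 40% of cells was taken. At 40% to 60% its error was larger than that of the other forms (a root mean square of 0.29 against 0.22 and 0.23), and no estimate is given there. Genes under 5% were not simulated. A form with 50 neighbours and a quantile set by 0.5 times the share of cells at zero is kept as a second alternative. For the simulation, the fl/fl library was split into 2598 reference cells and 1820 changed cells, with 200 genes changed in all cells and 200 in each of clusters 11, 12 and 16, and integrated with Seurat 5.3.0 in R 4.3.3. Clusters with fewer cKO than fl/fl cells had been thinned in the changed part. For genes above zero in 5% to 20% of cells, true and deposited-like differences had a correlation of 0.41 across gene and cluster pairs with a slope of 0.34, and the estimate had one of 0.93 with a slope of 0.81 and an SD of error of 0.060. The alternatives tried were resolutions 0.5 and 2, 15 components, clusters from the deposited UMAP, possible doublets left out, immune cells as the denominator, clusters made without the listed genes and Ahr, a mean trimmed by 5% at each end, division by the SD within the class, clusters weighted equally, the mean of list members, both forms of the removed correction, unnamed clusters joined to classes, and classes, and clusters 16 and 17, split into the clusters of the deposited UMAP, of 15 components or of resolution 2, each with at least 10 cells per library and weighted by its fl/fl cells.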

Results

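Single-cell RNA profiles were collected from whole pancreatic tumors of mice, 14 days after cells of MT4, a tumor organoid line from the KPC model of pancreatic adenocarcinoma, had been placed in the pancreas. Pooled tumors of 3 Ahr fl/fl mice gave 1 library, and pooled tumors of 3 mice that carried LysM-Cre beside the floxed Ahr alleles (Ahr cKO) gave the other. LysM-Cre acts mainly in macrophages, monocytes and neutrophils, and Ahr encodes the aryl hydrocarbon receptor, a transcription factor switched on by its ligands. The comparison asks how the cells of the tumor differ when Ahr is deleted in these myeloid cells. The values covered 2000 genes in 5196 cells of the fl/fl library and 4577 cells of the cKO library. The depth in molecules per cell is unknown. A fl/fl cell had a median of 108 of the 2000 genes above their zero level, and the 5th and 95th percentiles were 45 and 441 genes.

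All differences between the libraries are scaled differences, cKO minus fl/fl, in SDs of a gene over all cells, and not changes in expression. The cKO values had also been moved by a correction that varied over cells and genes. An estimate with this correction removed is therefore given beside the deposited difference, for genes above zero in under 40% of the fl/fl cells of every cluster of a class. In simulated libraries, for genes above zero in 5% to 40% of cells, the deposited differences had the right sign for 73.2% to 74.3% of gene and cluster pairs with a true difference of at least 0.2, and the estimate had it for 98.2% to 98.7%. Both simulated libraries came from the fl/fl library, so technical differences between libraries were not simulated. How accurate the estimate is in their presence is unknown. The simulated cells also kept their labels from the main clustering and were not clustered anew. The same simulation was used to choose the form of the estimate. The 98.2% to 98.7% can therefore be too high for these data. Estimates for genes under 5%, such as Ahr in Neutrophil-like, Birc5 in Macrophage-like and Scin in DC-like cells, were not covered by the simulation. A second form of the estimate is given for part of the genes where it differed. With 1 library per genotype no test was possible, no difference has a replicate check, and the intervals on shares cover counting error only.

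Ahr itself lies at positions 35497974 to 35535038 of chromosome 12 (GRCm38). It was above zero in 18.8% of Macrophage-like (exact 95% interval 15.6% to 22.3%), 18.8% of Monocyte-like, 19.4% of DC-like and 17.6% of Tumor epithelial-like fl/fl cells. Lower shares were found in T cell-like cells (8.97%), Cr2/Vpreb3 cells (3.07%) and Neutrophil-like cells (1.5%, 6 of 400). The level of background RNA was not measured. In the deposited values Ahr was higher in the cKO library in Macrophage-like cells, with a mean of 0.49 (SD 1.10 over 360 cells) against 0.35 (SD 1.23 over 538 cells), a difference of 0.14. Without the correction this difference was -0.068, and it was -0.058 in Monocyte-like, -0.018 in Neutrophil-like, -0.077 in T cell-like and 0.27 in Tumor epithelial-like cells. In the second form of the estimate Ahr was -0.11 in Macrophage-like and -0.13 in Monocyte-like cells, but also -0.10 in T cell-like and -0.084 in NK-like cells, which LysM-Cre does not mainly target, and -0.022 in Neutrophil-like cells. The Macrophage-like value stood at percentile 7.23 among 166 genes with a similar share of cells above zero. The deleted exons of Ahr are not given, and a 3' tag outside them checks nothing, so these values neither show nor exclude the deletion. Lyz2, the gene whose locus drives the Cre, lies at positions 117277331 to 117282321 of chromosome 10. Its deposited difference was -0.076 in Macrophage-like, 0.040 in Monocyte-like and 0.064 in Neutrophil-like cells, and it was above zero in 98.6% of Monocyte-like but also in 9.10% of T cell-like fl/fl cells. Of the genes that AHR induces, Cyp1b1 and Scin were the 2 measured members out of 9. In Macrophage-like cells the Cyp1b1 difference was -0.019 and Scin was at zero in the mean of both libraries. In DC-like cells Scin, which is also a leading gene of the migratory DC cluster, was 0.54 higher, and 0.49 higher with the correction removed.

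**Figure D1:**
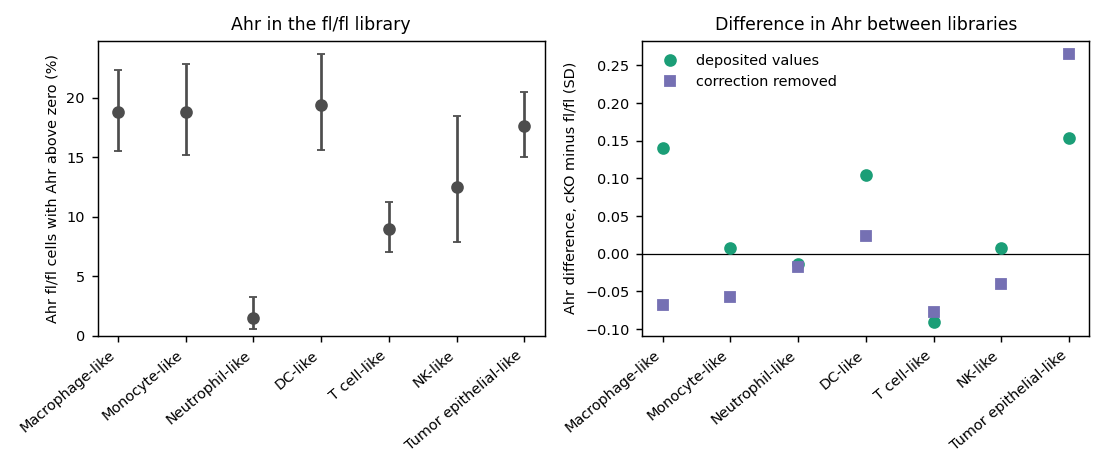
The left panel plots the percent of fl/fl cells with Ahr above zero per class, with exact 95% intervals, and the right panel the difference in Ahr between the libraries in SDs, from deposited values (circles) and with the correction removed (squares). In Macrophage-like cells the circle lies at 0.14 and the square at -0.068.

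Among all cells, the cKO library held fewer Tumor epithelial-like cells and fewer DC-like and Macrophage-like cells, and more T cell-like and Cr2/Vpreb3 cells. Tumor epithelial-like cells, marked by the keratins Krt8, Krt18 and Krt19, made up 14.9% of the fl/fl library (772 cells, 13.9% to 15.9%) and 3.95% of the cKO library (181 cells, 3.41% to 4.56%). The difference of -10.9 points was -6.95 points at a clustering resolution of 2, where a cluster led by Lmna, S100a6 and Krt18, with 247 fl/fl and 18 cKO cells, had its highest marker score for this class (0.454) but stayed under the 0.5 needed for a name. Macrophage-like cells made up 10.4% (9.54% to 11.2%) and 7.87% (7.10% to 8.68%), and DC-like cells 7.64% (6.93% to 8.40%) and 4.48% (3.90% to 5.12%). T cell-like cells made up 14.4% (13.4% to 15.4%) of the fl/fl library and 18.4% (17.2% to 19.5%) of the cKO library. Cr2/Vpreb3 cells, named after the complement receptor gene Cr2 and the B-lineage gene Vpreb3, made up 11.9% (11.03% to 12.8%) and 28.6% (27.3% to 29.9%). None of the 7 fixed B cell markers was measured, so the markers of this class were chosen after the data were seen. Monocyte-like (8.18% and 8.32%), NK-like (3.23% and 3.06%) and Neutrophil-like cells (7.70% and 8.56%) had overlapping intervals. Plasma cell-like cells made up 0.828% and 0.590%, and Erythroid-like cells 0.674% and 1.35%.

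Clusters that stayed unnamed made up 20.3% of the fl/fl and 14.9% of the cKO library. The largest of them, cluster 0, was led by Vim, Ccl2 and Cd14 and held 6.77% and 7.36%. Cluster 9, led by the granule protein genes Elane, Prtn3 and Mpo of early neutrophil development, held 3.21% (2.75% to 3.73%) and 1.22% (0.926% to 1.59%). Cluster 5, led by the later granule genes Camp, Ngp and Ltf, held 3.91% (3.40% to 4.47%) and 1.49% (1.16% to 1.88%). With clusters 5 and 9 joined to the Neutrophil-like class, that class went from 14.8% in fl/fl to 11.3% in cKO, the opposite direction to the class alone. Cluster 19, a mix of cycling cells led by Stmn1 and Pclaf, held 4.37% and 3.98%. Cluster 10, where hemoglobin genes and the collagen genes Col1a1 and Col3a1 led together, held 2.00% and 0.852%. At a clustering resolution of 2, a hemoglobin-led cluster held 49 fl/fl and 30 cKO cells. A cluster led by Sparc, Col1a1 and Col3a1, named Fibroblast-like there, held 55 and 9. Among immune cells alone, Macrophage-like cells were 12.6% and 8.38%, DC-like 9.26% and 4.77%, Monocyte-like 9.92% and 8.87%, T cell-like 17.4% and 19.6%, and Cr2/Vpreb3 cells 14.4% and 30.4%. A sort for live cells was the only one named for these samples, so the shares also carry how much tumor and neighbouring tissue went into each pool.

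**Figure D2:**
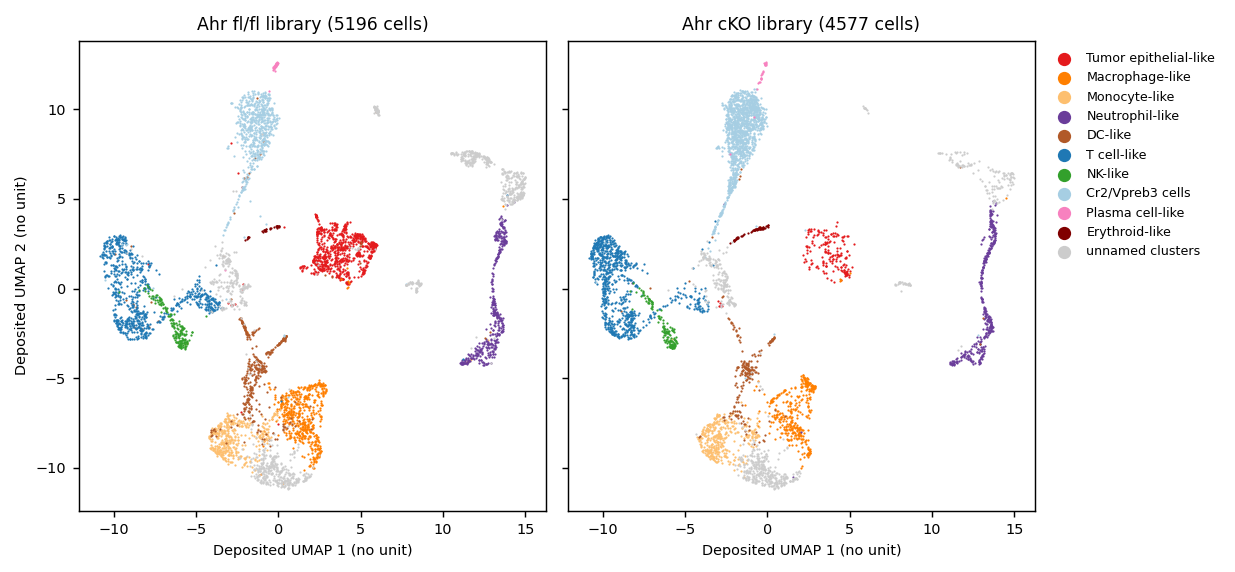
Each point is 1 cell at its deposited UMAP coordinates (no unit), colored by cell class, with the 5196 fl/fl cells on the left and the 4577 cKO cells on the right. The Tumor epithelial-like group is sparser (181 against 772 cells) and the Cr2/Vpreb3 group denser (1307 against 618 cells) in the cKO library.

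**Figure D3:**
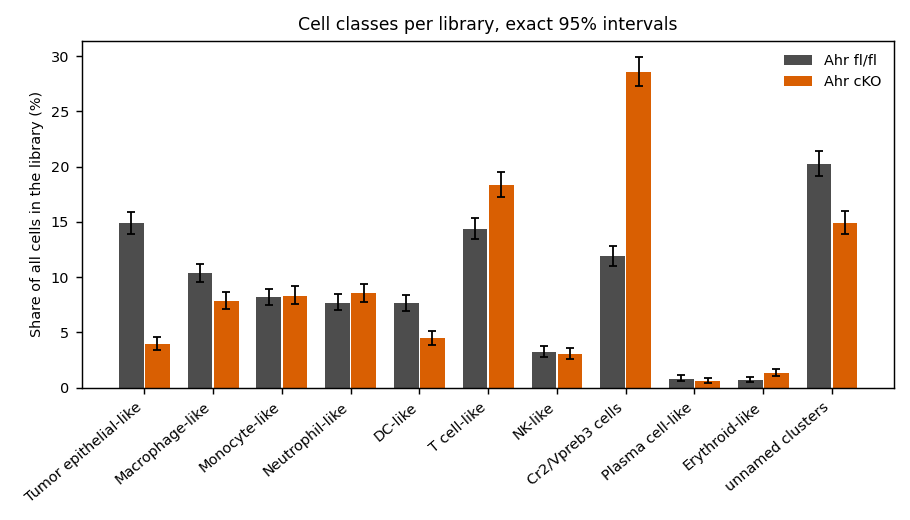
Bars give each class as a percent of all cells of its library, fl/fl in grey and cKO in orange, and lines the exact 95% intervals for counting error. Tumor epithelial-like cells stand at 14.9% and 3.95%, and Cr2/Vpreb3 cells at 11.9% and 28.6%.

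Macrophage-like cells of the cKO library had higher deposited values of the complement genes C1qc (0.57) and C1qa (0.42), the lipid carrier gene Apoe (0.54) and the adhesion gene Vcam1 (0.56). Lower values were found for the chemokine receptor gene Ccr2 (-0.32), which marks cells recently derived from monocytes, and for Tgfbi (-0.27). Of 5 complement genes, 3 were higher by at least 0.1 and C3ar1 was lower (-0.26). Their median was 0.35, at percentile 99.6 among 10000 random lists of matched level, their mean was 0.21, and C1qa, C1qb and C1qc are also markers of the class. Of 9 alternative activation genes, 5 were higher and none was lower, with a median of 0.15 (percentile 99.4), among them the lectin genes Mgl2 (0.37) and Mrc1 (0.34) and the arginase gene Arg1 (0.32). With the correction removed, Mgl2 (0.20) and Mrc1 (0.25) stayed higher, while Ccl24 went from 0.25 to -0.041 and the median of the 8 members with an estimate from 0.12 to -0.019. Vcam1 (0.24), the transferrin gene Trf (0.54 deposited, 0.26 removed) and Hebp1 (0.42, 0.21) kept their sign, as did the lower Ass1 (-0.23, -0.20), Rexo2 (-0.21, -0.23) and Cysltr1 (-0.25, -0.14). Fndc3b (-0.30, 0.16) and Htra2 (-0.21, 0.14) did not, though both were within 0.1 of zero in the second form, and Ltc4s (0.44, 0.044), Slc7a2 (0.43, -0.036), Itga9 (0.43, -0.013), Ccl12 (-0.25, 0.020) and Nrg1 (-0.28, 0.032) came close to zero. In the second form Slc7a2 was -0.16, Itga9 -0.18, Ccl12 -0.11 and Nrg1 -0.12. C1qc, C1qa, Apoe, Sdc3 (0.44), Ccr2, Tgfbi and C3ar1 were above zero in too many cells for an estimate. The complement and Apoe differences went with the makeup of the class in part, and how far depended on the subclusters used. With clusters from 15 components, the cluster led by C1qa, C1qc and Apoe held 148 fl/fl and 159 cKO cells of the class, and the cluster led by Arg1 and Fn1 held 333 and 182. With the subclusters weighted as in the fl/fl library, C1qc was 0.23 higher by UMAP clusters and -0.059 by 15-component clusters, Apoe 0.058 and 0.025, and the complement median 0.12 and -0.20. Vcam1 (0.28 both ways) and Tgfbi (-0.27 and -0.35) kept their sign, as did Mrc1 (0.20 and 0.14). At a clustering resolution of 2, the cluster led by C1qa, C1qb and C1qc held 278 fl/fl and 180 cKO cells of the class. The cluster led by Arg1 and Fn1 held 240 and 176. With the fl/fl makeup of resolution 2 clusters the complement median stayed within 0.1 of 0.35. Such subclusters rest partly on the same genes, so this weighting can also take away a difference within cells.

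The other lists gave smaller medians in Macrophage-like cells. MHC class II genes had a median of 0.13 (3 of 5 higher, percentile 85.1), or -0.090 with the fl/fl makeup of 15-component clusters, with H2-Eb1 at 0.23 and its activator Ciita at 0.098 deposited and -0.18 with the correction removed. With the fl/fl makeup of UMAP or resolution 2 clusters the MHC class II median stayed within 0.1 of 0.13. The inflammatory cytokines and mediators had a median of -0.013 over 11 genes, with Nos2, which makes nitric oxide, at 0.16 (0.065 removed) and Il1a at -0.071 (0.12 removed, -0.042 in the second form). Medians were 0.031 for 13 interferon response genes, 0.007 for 9 lipid-associated macrophage genes, -0.022 for 12 myeloid chemokine genes and -0.003 for 9 hypoxia and glycolysis genes. The 12 cell cycle genes had a median of 0.045 (3 higher, none lower, percentile 99.5), and 0.056 over 11 with the correction removed (4 higher, percentile 97.9), with Birc5 at 0.195 (0.24 removed) and Stmn1 at 0.13 (0.17 removed). The 7 dissociation and stress genes had a median of -0.040. Among 566 genes above zero in at least 5% of Macrophage-like fl/fl cells, the deposited and removed differences had a correlation of 0.29 across genes, which are not independent replicates.

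Monocyte-like cells of the cKO library had higher values of Ace (0.37), Nr4a1 (0.25) and Klf4 (0.21). Ace and Nr4a1 are known from patrolling monocytes. Once the correction was removed, Ace (0.31), the iron regulator gene Hfe (0.31 deposited, 0.38 removed), Grk3 (0.26, 0.20), Klf9 (0.25, 0.24) and Trf (0.26, 0.13, or 0.086 in the second form) stayed higher, Tmem176a (0.23, 0.10, or 0.074 in the second form) was at the limit of 0.1, Pdlim1 (0.21, 0.018) came close to zero, and Nr4a1, Klf4 and Calr (0.20) had no estimate. The lowest deposited values were small. Fam102b (-0.18, 0.15), Jaml (-0.17, 0.17) and Idi1 (-0.12, 0.13) changed sign but were within 0.1 of zero in the second form, Tnip3 (-0.15, 0.050), Svip (-0.13, 0.015) and Hspa9 (-0.12, 0.046) came close to zero, none of the 8 lowest genes with an estimate stayed lower by 0.1 (Svip at -0.11, and Pltp and Ncoa7 at -0.12, did in the second form), and Fam26f (-0.16) and Gpr141 (-0.14) had no estimate. Every list had a median between -0.027 (9 hypoxia and glycolysis genes) and 0.075 (7 dissociation and stress genes, led by Hspa1b at 0.14, or 0.062 with the correction removed).

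Neutrophil-like cells of the cKO library had lower deposited values of hypoxia and glycolysis genes and higher values of single granule protein genes such as Ngp, Camp and Ltf. The highest genes included Ifitm6 (0.52), Chil1 (0.52), Ngp (0.45), Anxa1 (0.39), Camp (0.39), Ltf (0.37), Padi4 and Orm1. Only 2 of the 10 highest had an estimate, and Padi4 (0.42, 0.22) stayed higher with the correction removed while Orm1 (0.37, 0.046) came close to zero. The lowest genes included the ferritin gene Fth1 (-0.42), Gadd45b (-0.32, -0.52), the niacin receptor gene Hcar2 (-0.27, -0.36), Fam162a (-0.27, -0.29), Acod1, which makes itaconate (-0.26, -0.56), and Cd274, which encodes PD-L1 (-0.24, -0.20). Of 9 hypoxia and glycolysis genes, 4 were lower by at least 0.1 and none was higher, with a median of -0.097 at percentile 0.495. Over the 7 with an estimate, the median was -0.12 with and without the correction, and Ero1l (-0.21, -0.24), the glucose transporter gene Slc2a1 (-0.16, -0.12), Egln3 (-0.15, -0.12) and Bnip3 (-0.12, -0.17) were lower both ways. Of 11 inflammatory genes, 4 were lower, among them Cxcl2 (-0.20) and Il1b (-0.13), neither with an estimate, with a median of -0.033 at percentile 2.605. The other 2, Il1a (-0.13, -0.027) and Tnf (-0.11, -0.060), were within 0.1 of zero with the correction removed, where none of the 9 genes with an estimate was lower and the median was 0.000 at percentile 25.7. In the second form 3 of these 9 were lower, among them Il1a (-0.105) and Tnf (-0.12), and the median was -0.002 at percentile 49.0. Prkar2b changed sign (-0.31, 0.15, or 0.067 in the second form), and Gm5483 (-0.25, 0.072) came close to zero. The class joined cluster 12, led by Csf3r and Cxcr2 (277 fl/fl and 248 cKO cells), and cluster 7, led by Ifitm6, Ltf and Ngp (123 and 144 cells), so genes that lead cluster 7 also carried its larger number of cKO cells. The unnamed cluster 5, led by Camp, Ngp and Ltf, held 203 fl/fl and 68 cKO cells. These cells lay outside the class, so the higher granule gene values do not cover them. A subcluster of the deposited UMAP with Hcar2, Upp1, Fth1 and Gadd45b among its 10 leading genes held 89 fl/fl and 63 cKO cells of the class. One led by Mmp8 and Ifitm6 held 42 and 75. Such subclusters rest partly on the same genes as the differences. Their sizes, and the weighting below, therefore cannot separate makeup from a difference within cells. With subclusters weighted as in the fl/fl library, the hypoxia and glycolysis median was 0.011 by UMAP and -0.042 by 15-component clusters, and -0.040 with clusters 7 and 12 weighted equally. The same weighting gave -0.005 and -0.12 for Hcar2, -0.019 and -0.085 for Acod1, -0.20 and -0.28 for Fth1, and 0.12 and -0.018 for Ngp.

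**Figure D4:**
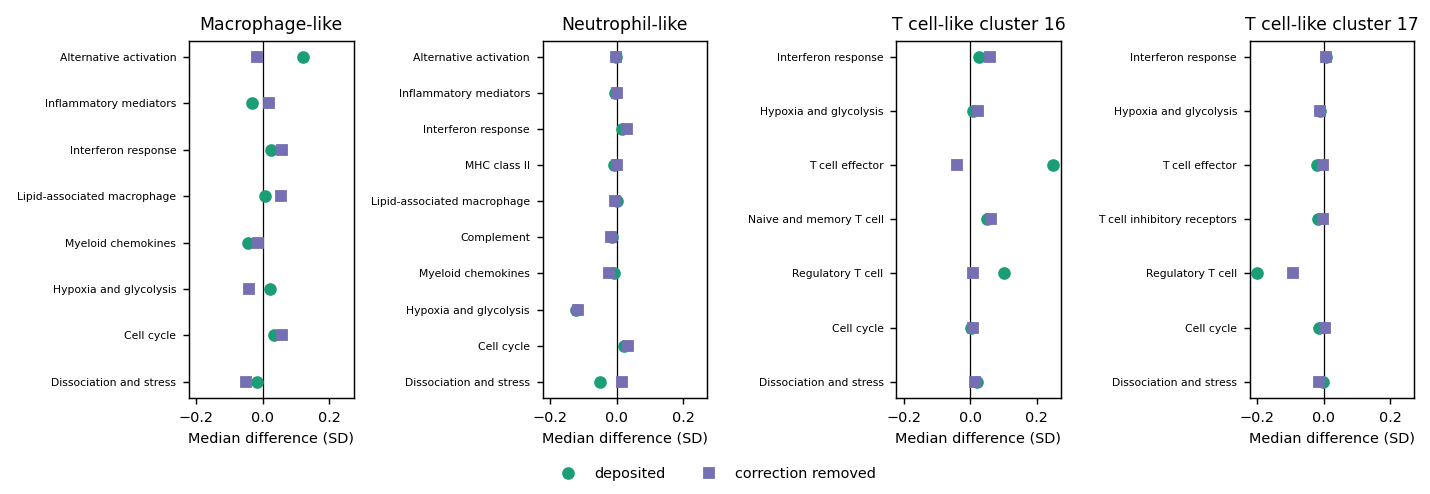
Each panel plots, for 1 class or cluster, the median difference of the members of each gene list in SDs, from deposited values (circles) and with the correction removed (squares), over the same members of lists with at least 3 of them. In Neutrophil-like cells the hypoxia and glycolysis median lies at -0.12 both ways, and in cluster 16 the T cell effector median goes from 0.25 to -0.039.

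DC-like cells of the cKO library had higher values of the growth factor receptor gene Flt3 and of Clec9a, and lower values of Ccr7. Flt3 was 0.93 higher (0.60 with the correction removed), Ppp1r14a 0.56 (0.96), Dnase1l3 0.46 (0.58), Clec9a, a receptor for dead cells, 0.44 (0.37), and Sept3 0.43 (0.42). Tnni2 (0.58, 0.36) and Snx22 (0.43, 0.475) fell to 0.029 and 0.091 in the second form of the estimate. Flt3 and Clec9a are also markers of the class. Qpct (0.48, 0.072) came close to zero with the correction removed, and Ckb (0.73) and Bcl2a1d (0.47) had no estimate. Lower values were found for Mmp12 (-0.20, -0.21), Slamf9 (-0.19, -0.25), Mcm4 (-0.21, -0.18), Etv3 (-0.31) and Ccr7 (-0.20), while Adam23 changed sign (-0.20, 0.50) and Cacybp (-0.22, 0.012), Nr4a2 (-0.20, 0.013) and Pltp (-0.21, -0.052) came close to zero, the last 2 at -0.11 in the second form. MHC class II genes were higher in 4 of 5, with a median of 0.25 (percentile 98.5). With the clusters of the class weighted equally that median was -0.072, the opposite sign, at a clustering resolution of 2 it was 0.135, and with the fl/fl makeup it was -0.073 by UMAP and -0.003 by 15-component clusters. Cluster 3, led by H2-DMb1, Cd209a and Clec10a, held 173 fl/fl and 71 cKO cells. Cluster 18 held 174 and 112 and was led by Cst3, Plet1 and the MHC class II genes H2-Ab1, H2-Eb1 and H2-Aa. Ppp1r14a and Naaa were also among the 10 leading genes of cluster 18. The migratory cluster 14, led by Ccr7 and Fscn1, held 50 and 22. A subcluster of the deposited UMAP led by Cst3, Plet1 and Ckb held 100 and 88 cells of the class, and one led by Cd209a 81 and 32. Single genes such as Flt3, Clec9a, Ppp1r14a and Dnase1l3 can carry this makeup. The estimate with the correction removed does not even it out.

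T cell-like cells of the cKO library had higher values of genes of naive and memory T cells and lower values of cell cycle genes. Of 4 naive and memory genes, 3 were higher, with a median of 0.30 that lay above every one of the 10000 random lists (percentile 100), among them the transcription factor genes Lef1 (0.56) and Tcf7 (0.43) and the homing receptor gene Ccr7 (0.16, or 0.145 with the correction removed and 0.093 in its second form). Of 12 cell cycle genes, 9 were lower, with a median of -0.17, among them Stmn1 (-0.24), Mki67 (-0.24) and Top2a (-0.23). These medians moved with the makeup of the class. With the clusters of the class weighted equally they were 0.029 and 0.041, and at a clustering resolution of 0.5 the cell cycle median was -0.015. With the fl/fl makeup of subclusters the naive and memory median was 0.046 by UMAP and 0.11 by 15-component clusters, and the cell cycle median 0.047 and 0.018. Cluster 17, led by Tcf7, Lef1 and Il7r, held 6.64% of the fl/fl library (345 cells, 5.98% to 7.35%) and 11.6% of the cKO library (532 cells, 10.7% to 12.6%). Cluster 15, of cycling cells led by Cd8a and Top2a, held 2.62% (136 cells) and 1.40% (64 cells), and cluster 16, led by Cxcr6, Nkg7, Lag3 and Cd8a, 5.12% (266 cells) and 5.33% (244 cells). Cd160 (-0.39, -0.27), Nrgn (-0.26, -0.25) and the chemokine gene Xcl1 (-0.25, -0.255) were lower both ways, Gm12840 (0.34, 0.21) was higher both ways, Dapl1 (0.38, 0.068), Izumo1r (0.30, -0.012) and Cd5 (0.26, -0.016) came close to zero, so that 3 of the 6 highest genes with an estimate stayed higher by 0.1 (Gm12840 alone in the second form, where Izumo1r was -0.12), and Tacc2 (-0.33, 0.27, or 0.039 in the second form) and 1700097N02Rik (-0.32, 0.17, or -0.037) changed sign. Medians over the class were -0.075 for 11 effector genes, -0.077 for 4 inhibitory receptor genes, -0.037 for 6 regulatory T cell genes and 0.033 for 13 interferon response genes.

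Clusters 16 and 17 were compared on their own, a choice made after their makeup had been seen. In cluster 16, 9 of 11 effector genes were higher in the deposited values of the cKO library, with a median of 0.29 (percentile 99.99), among them the interferon gamma gene Ifng (0.51) and the granzyme gene Gzmb (0.46). Without the correction, Ifng was -0.38 and Gzmb -0.082, and the median of the 6 members with an estimate went from 0.25 to -0.039. Of these 6, 2 were higher by at least 0.1 and 1 was lower, in both forms of the estimate. The inhibitory receptor genes had a median of 0.31, with Lag3 at 0.55 and no estimate, while Ctla4 (0.33, 0.49) was higher both ways and Tox (0.28, -0.30) changed sign. At a clustering resolution of 2 the cells of cluster 16 fell mainly into subclusters led by Cd8a and Nkg7 (181 fl/fl and 146 cKO cells) and by Cxcr6 and Cd4 (81 and 93). The regulatory T cell genes scored 0.20 in the first and 1.19 in the second, so Ctla4 can also carry this makeup. In cluster 17, 4 of 6 regulatory T cell genes were lower and none was higher, with a median of -0.20 (percentile 0.010) in the deposited values and -0.091 with the correction removed. They included the transcription factor genes Ikzf2 (-0.25, -0.42) and Foxp3 (-0.25, -0.007, or -0.18 in the second form) and the receptor gene Tnfrsf18 (-0.30, -0.12). At a clustering resolution of 2 the cells of cluster 17 fell into subclusters led by Ms4a4b and Ikzf2 (102 fl/fl and 76 cKO cells), by Lef1 and Tcf7 (153 and 310) and by Ikzf2 and Tnfrsf4 (90 and 146). With the fl/fl makeup of these subclusters the regulatory T cell median was -0.18 and Ikzf2 -0.20, and the median was -0.185 by UMAP and -0.23 by 15-component clusters. Naive and memory genes had a median of 0.14 in cluster 17 (0.045 with that makeup), with Lef1 at 0.46 and Il7r at -0.35. Ahr was -0.084 deposited and -0.094 with the correction removed in cluster 17, at percentile 1.65 among 729 genes of similar detection. It was above zero in only 19 of 345 fl/fl cells there (5.51%, 3.35% to 8.47%). The matched genes lay within 5 points of that share, a range that reaches below the genes covered by the simulation.

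Tumor epithelial-like cells of the cKO library had lower deposited values of cell cycle genes. Of 12 members 7 were lower and none was higher, with a median of -0.12 (percentile 0.13), and over the 10 members with an estimate it was -0.11 deposited and -0.15 with the correction removed. The topoisomerase gene Top2a (-0.26, -0.24) and Birc5 (-0.18, -0.25) were among them, and Cdk1 was -0.18 (-0.053 removed). The hypoxia and glycolysis genes were mixed, with 4 of 9 higher and 2 lower, from Ldha at 0.39 to Ero1l at -0.26 (-0.12 removed). Over the 7 members with an estimate the hypoxia and glycolysis median was 0.004 deposited and 0.13 with the correction removed (4 higher, 1 lower), or 0.083 in the second form (2 higher, 2 lower). The interferon-induced chemokine gene Cxcl10 was lower (-0.405, -0.46), while Hspa1b went from -0.29 to 0.49, or to 0.040 in the second form. Subclusters of these cells differed between the libraries. A subcluster of the deposited UMAP led by Iigp1, Cxcl10 and Cenpe held 77 fl/fl cells and 1 cKO cell, and with 15 components a subcluster led by Clu, Lmna and Spp1 held 364 and 19. With the fl/fl makeup of the subclusters that both libraries filled, the cell cycle median was -0.020 by UMAP, -0.18 by 15-component and 0.016 by resolution 2 clusters, Top2a was -0.19 and -0.35 by the first 2, and Cxcl10 -0.26 and -0.51. Across 1079 genes the deposited and removed differences had a correlation of 0.11, the lowest of the 7 classes. NK-like cells, with 168 and 140 cells, had higher values of Il7r (0.30, 0.28) and of the perforin gene Prf1 (0.17), and lower values of the stress gene Fosb (-0.33, -0.28). The largest deposited difference among their listed genes, that of Ikzf2 (0.59), changed sign with the correction removed (-0.20). The 4 naive and memory genes had a median of 0.20 in NK-like cells, or 0.068 with the correction removed.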

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

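The removal of the correction, in both forms, the joining of unnamed clusters to classes, and the weighting of subclusters as in the fl/fl library were chosen only after the results had been seen, and the other settings were planned. Where the intervals of a class did not overlap, the direction of its share difference held under the other clusterings and without possible doublets. These clusterings were resolutions 0.5 and 2, 15 components, the deposited UMAP and clusters without listed genes. Monocyte-like, NK-like and Neutrophil-like cells had overlapping intervals. Their differences stayed within counting error of the main values there, and a change of sign was not scored. The Tumor epithelial-like difference moved from -10.9 points to -6.95 at resolution 2, where a cluster of 247 fl/fl and 18 cKO cells missed the name of the class. The T cell-like difference moved to 5.54 points without the listed genes. Among immune cells alone the differences were -4.17 points for Macrophage-like, -1.05 for Monocyte-like, -4.49 for DC-like and 2.12 for T cell-like cells, and for Neutrophil-like cells -0.208, so that the Monocyte-like (0.145) and Neutrophil-like differences changed sign. The Neutrophil-like difference of 0.866 points became -1.55 with cluster 5 joined and -3.55 with clusters 5 and 9 joined, since both clusters held fewer cKO cells.

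Under the planned settings tried for it, the Ahr difference stayed within 0.1 of its main value in all 7 classes. With the correction removed it was -0.068 in Macrophage-like and 0.265 in Tumor epithelial-like cells, and with the adaptive quantile -0.109 in Macrophage-like, -0.130 in Monocyte-like and -0.004 in DC-like cells. List medians with the correction removed, and then with the adaptive quantile, were -0.019 and -0.031 for alternative activation in Macrophage-like cells, 0.068 and 0.019 for naive and memory genes in NK-like cells, -0.039 and -0.059 for effector genes in cluster 16, and 0.008 and -0.043 for regulatory T cell genes in cluster 16, and -0.091 and -0.169 for regulatory T cell genes in cluster 17. These medians cover only members with an estimate. With clusters weighted equally the medians were -0.072 for MHC class II in DC-like, 0.029 for naive and memory and 0.041 for cell cycle genes in T cell-like cells. The MHC class II median in DC-like cells was 0.135 at resolution 2, the cell cycle median in T cell-like cells -0.015 at resolution 0.5, and the mean of the complement genes in Macrophage-like cells 0.208. Weighted to the fl/fl makeup of UMAP subclusters, and then of 15-component subclusters, the Ahr difference in Tumor epithelial-like cells was 0.31 and 0.537, and medians were 0.117 and -0.197 for complement in Macrophage-like, -0.073 and -0.003 for MHC class II in DC-like, 0.046 and 0.111 for naive and memory and 0.047 and 0.018 for cell cycle genes in T cell-like cells. The MHC class II median in Macrophage-like cells was -0.090 by 15-component subclusters, the hypoxia and glycolysis median in Neutrophil-like cells 0.011 by UMAP subclusters, and the inhibitory receptor median in cluster 16 0.168 by UMAP and 0.202 by 15-component subclusters. By resolution 2 subclusters, medians were -0.075 for MHC class II in DC-like, 0.017 for naive and memory and 0.010 for cell cycle genes in T cell-like cells, 0.016 for cell cycle genes in Tumor epithelial-like cells and 0.399 for effector genes in cluster 16. The regulatory T cell median in cluster 17 stayed within 0.1 of -0.20 by all 3 kinds. The cause of these shifts was not tested, beyond what each setting's construction shows.

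Of the 50 single genes followed, which were the 5 from each end in the 5 classes with named extremes, none changed sign under a planned setting, but 24 moved by over 0.1 with clusters weighted equally, 16 with the trimmed mean and 35 when divided by the SD within the class. Division by that SD changes the unit, so the 35 moves do not measure how stable these genes are. By 15-component subclusters weighted as in fl/fl, 3 changed sign, namely C1qc (-0.059) in Macrophage-like and Ifitm6 (-0.056) and Ngp (-0.018) in Neutrophil-like cells, and 23 more moved, by UMAP subclusters 26 moved and none changed sign, and by resolution 2 subclusters Txk (-0.016) in T cell-like cells changed sign and 22 moved. With the correction removed, 8 of the 32 with an estimate stayed within 0.1 of their main value and 14 moved by over 0.1. The other 10 changed sign. These were Adam23 (0.502) and Cacybp (0.012) in DC-like, Fndc3b (0.157) and Nrg1 (0.032) in Macrophage-like, Fam102b (0.145), Jaml (0.165) and Tnip3 (0.050) in Monocyte-like, Prkar2b (0.152) in Neutrophil-like, and 1700097N02Rik (0.169) and Tacc2 (0.269) in T cell-like cells. With the adaptive quantile 7 stayed within 0.1 and 16 moved. The other 9 changed sign, namely Adam23 (0.30) and Qpct (-0.051), Fndc3b (0.046) and Ltc4s (-0.053), Fam102b (0.009) and Jaml (0.052), Prkar2b (0.067), and Dapl1 (-0.084) and Tacc2 (0.039). The difference in the share of cells above zero, planned for single genes and Ahr, was not run, since the cKO library keeps no zero level. No paired analysis was possible because each genotype has 1 library. The unknown depth limits what low shares, as of Ahr in Neutrophil-like cells, can show.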

Other observations

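Of the tests below, the search for keratin-positive cells outside the tumor clusters was set before its result was seen, and the others were chosen only after the results were seen. In the fl/fl library, where a zero level exists, genes of the Y chromosome separated the tumor cells from the rest of the tissue. Ddx3y was above zero in 27.3% of Tumor epithelial-like cells (24.2% to 30.6%) and in 0.226% of the other cells (0.108% to 0.415%). Eif2s3y was above zero in 25.4% against 0.226%, and Uty in 15.5% against 0.113%.

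The share of Tumor epithelial-like cells was 14.9% in the fl/fl and 3.95% in the cKO library. Dilution by more lymphoid cells was argued against as the whole cause, since with T cell-like and Cr2/Vpreb3 cells left out the shares were 20.2% and 7.45%, a difference of -12.7 points. Tumor cells placed in other clusters were searched for by at least 2 of Krt8, Krt18 and Krt19 well above the fl/fl zero level. Outside the tumor clusters such cells made up 0.565% in fl/fl and 0.0910% in cKO, a difference of -0.474 points with no excess in cKO. Inside them the shares were 69.0% and 75.1%. The correction moved cKO values and could have lowered keratins in misplaced cells, so the search cannot exclude them. Different amounts of tumor and of neighbouring lymphoid tissue in the pools cannot be told apart from an effect of the genotype, since there was 1 pool per genotype. The genotype stays open as a biological explanation that was not tested.

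Deposited values of T cell effector genes in cluster 16 and of alternative activation genes in Macrophage-like cells were higher in the cKO library. A candidate explanation is that the integration step raised them. With the correction removed, the medians of the same members were -0.039 in cluster 16, from 0.25, and -0.019 in Macrophage-like cells, from 0.12. The explanation needs such a fall, but this check was set after the medians had been seen, so it cannot decide. In cluster 16 it also covers only 6 of the 11 effector genes. The values of Mgl2 (0.20) and Mrc1 (0.25) stayed higher without the correction, so the integration step would not account for these 2 genes. In cluster 16, 2 of the 6 effector genes with an estimate were higher by at least 0.1 without the correction, and 1 was lower. An effect of the genotype on these cells was not tested by a second pool and stays open.

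Ahr was not lower in the deposited values of Macrophage-like cells of the cKO library. The integration step could hide a loss of the gene's signal, and with the correction removed the difference was -0.068, or -0.109 in the second form. A true loss of 0.5 times the fl/fl mean, -0.176, would be read as -0.113 by the first form with its simulated slope of 0.81, and no loss as 0.030, with an SD of error of 0.060. The value of -0.068 lies between these, so it does not settle which holds. That SD of error also leaves out technical differences between real libraries. A 3' tag outside the deleted exons, and background RNA, remain open as well.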
